A study of Mus musculus with 6 samples.

How the data were processed

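Gene expression was measured by RNA sequencing in the livers of 6 mice aged 8 weeks and kept on normal chow. Of these, 3 were Nogo knockout mice and 3 were wild-type littermates, per the labels. Nogo is the protein product of the gene Rtn4, a reticulon that shapes the membrane of the endoplasmic reticulum. RNA was extracted with a Qiagen RNeasy kit and libraries were made from total RNA with a SMARTer mRNA-Seq kit, per the labels' protocols. The authors deposited a table of raw counts per gene, with whole numbers, 1 column per mouse and no normalization in the values. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation, the strandedness and the treatment of reads that match several genes are not given in the sources used here. Reads that match several genes may be dropped or split in such counts, so the level of a gene with near-identical copies can be too low.

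The table held 54232 genes, each with a name and an identifier, and no row without a gene name. Of the identifiers, 54165 were found in GENCODE release M21, an annotation of the same build, which supplied coordinates, biotypes, transcript lengths and GC content. Among the tested genes, 13300 had a match. There were 98 symbols that named more than 1 row. Library totals ran from 17568223 to 20902369 counts. A floor of 3 counts corresponded to 0.144 to 0.171 CPM (counts scaled to a common library size), and such floors cover counting error only, since the reads carry no molecular identifiers. A chi-square comparison of the counts of each pair of libraries of 1 genotype gave chi-square values of 23.1 to 190.1 per degree of freedom, where sampling noise alone gives about 1, so each library was counted as a separate sample. The labels describe the samples as livers of mice, and the p-values measure the spread between these 3 samples of each genotype.

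Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16 with its quasi-likelihood F test, TMM scaling and the filterByExpr filter, which kept 13304 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and the words rose and fell are kept for called genes. Fold changes are knockout over wild type on the log2 scale. The standard error (SE) was taken as the absolute log2 fold change divided by the square root of F. Levels are CPM after TMM scaling, given as mean ± SD over the 3 libraries of a genotype. Changes in single libraries, such as the medians of a list in 1 library, were taken from log2 of CPM plus 0.5, minus the wild-type mean. The added 0.5 shrinks them for genes of low level, so they can be smaller than the log2 fold changes of edgeR. No covariate was used. The labels number the wild-type libraries 2, 4 and 11 and the knockout libraries 1, 2 and 4, and nothing in the labels says that a number marks a litter.

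Before the data were examined, 39 gene lists were fixed, covering liver metabolism, insulin action and markers of the cell types a piece of liver can hold. The 36 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. Camera asks whether a list's genes lie higher or lower than all other tested genes, and an inter-gene correlation of 0.01 was preset. P-values were adjusted over the 36 lists. The same test with a correlation estimated from the data, and fry, stood beside it. Counts of changed members were also made with p-values adjusted over the list alone. Another 3 lists, of mitochondrially encoded mRNAs, cytosolic ribosomal proteins and nuclear-retained RNAs, were written after the data had been examined, and were adjusted among themselves.

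Genes to be named were chosen by a rule fixed before the data were examined. It took Rtn4, then the 10 called genes with the largest rise and the 10 with the largest fall. These needed a mean of at least 1 CPM in the higher genotype, groups that did not overlap, and a symbol that was not a clone or pseudogene name. It then took up to 4 called members of each biology list and up to 3 of each marker list, by smallest p. Where no member of a biology list was called, up to 2 were taken. Insr, Irs1, Irs2, Akt2, Foxo1, G6pc, Pck1, Srebf1 and Fasn were among those always included. The rule named 136 genes, of which the text gives a part, and some are not reported here. Prkce, Enpp1, Akr1c6, Clec4g, Ptprb, Clu, Saa3, Hamp, Orm1, Orm3, Ugt1a1, Nr1i2, Aldoa, Gapdh, Hsph1, Ier2, Neat1, Rn7sk, Firre, Snhg11, Snhg14, Rpl3, Ndufb7, Atp5b, Hbb-bs, Ddx3y, Ctrb1, Mttp, Abca1, Scarb1 and the mitochondrial genes other than mt-Co2 were named after their values were seen.

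The main test was checked on simulated counts drawn from the means and totals of the real libraries, with 13304 genes of which 100 were changed 2-fold and 100 were changed 4-fold. It recovered 41.0% of the 2-fold and 82.0% of the 4-fold changes. Of its 131 calls, 8 (6.11%) were false. In simulated lists of 30 genes shifted by 0.5 on the log2 scale, camera found 5 of 5, with either correlation, and called 0 of 15 unshifted lists. The simulated genes were drawn independently of each other. This check therefore cannot show how often camera errs where the genes of a list vary together, as they may in the real lists.

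The alternatives fixed before the data were examined were scaling by median-of-ratios size factors and by upper quartiles, no low-count filter, and a filter of at least 1 CPM in 3 libraries. They also included DESeq2 1.42.0, limma-voom, robust dispersion, other thresholds, each library left out in turn, and the shared numbers 2 and 4 as a replicate block. That block used only 4 libraries and pairs mice by a number not known to mark pairs, so its passes carry little weight. After the data had been examined, 6 more were added. These were knockout 4 alone against wild type, where the lone library is assumed to vary like the wild types, mitochondrial genes left out, and the mitochondrial share of each library as a covariate. The others removed smooth length and GC trends from each library with mgcv 1.9.3, scaled by library totals, or left Rtn4 out of the list that holds it. Genes that share sequence were found by looking up every word of 50 bases of their transcripts in those of all other genes. There were 0 sample columns of other studies.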

Results

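Livers of Nogo knockout mice and of wild-type littermates were compared by RNA sequencing, with 3 mice of each genotype. The study's title names the effect of Nogo deficiency on the insulin signalling pathway as its question. The wild-type libraries are called wild type 2, 4 and 11 and the knockout libraries knockout 1, 2 and 4, after the numbers in their labels. They held 19218491, 17568223 and 20902369 counts in wild type and 18118811, 17732133 and 17654412 counts in knockout. At this depth 18653 to 19377 genes had at least 1 count.

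Rtn4, the gene that encodes Nogo, was read first as a check of the labels. It lies on chromosome 11 from 29692947 to 29744331 on the plus strand (mm10) and is a protein-coding gene, ENSMUSG00000020458. Its level was 40.5, 52.9 and 56.0 CPM in the wild-type libraries and 4.64, 8.22 and 4.69 CPM in the knockout libraries. The raw counts behind these levels were 852, 991 and 1205 in wild type and 70, 153 and 78 in knockout. The means were 49.8 ± 8.20 and 5.85 ± 2.05 CPM (SD, n = 3 each), a log2 fold change of −3.08 with an SE of 0.26 (edgeR, adjusted p = 0.00101). All 6 libraries thus carried the Rtn4 level of their labelled genotype. The labels do not state which part of the gene was removed, and counts per gene do not show on which exons the remaining 70 to 153 counts lie. Among 17 tested reticulons, Nogo receptors and partner proteins, 3 fell and 0 rose, and 5 fell and 0 rose when adjusted over the list alone. Besides Rtn4 these were Atl3, which encodes an atlastin that fuses membranes of the endoplasmic reticulum (−1.04 ± 0.19 SE), and Ormdl2, a regulator of sphingolipid synthesis (−1.87 ± 0.39). With Rtn4, the deleted gene, left out of it, the list had a mean of −0.35 and did not pass camera (adjusted p = 0.0849; adjusted p = 0.0321 with Rtn4 in the list, and 0.9 with an estimated correlation).

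**Figure D1:**
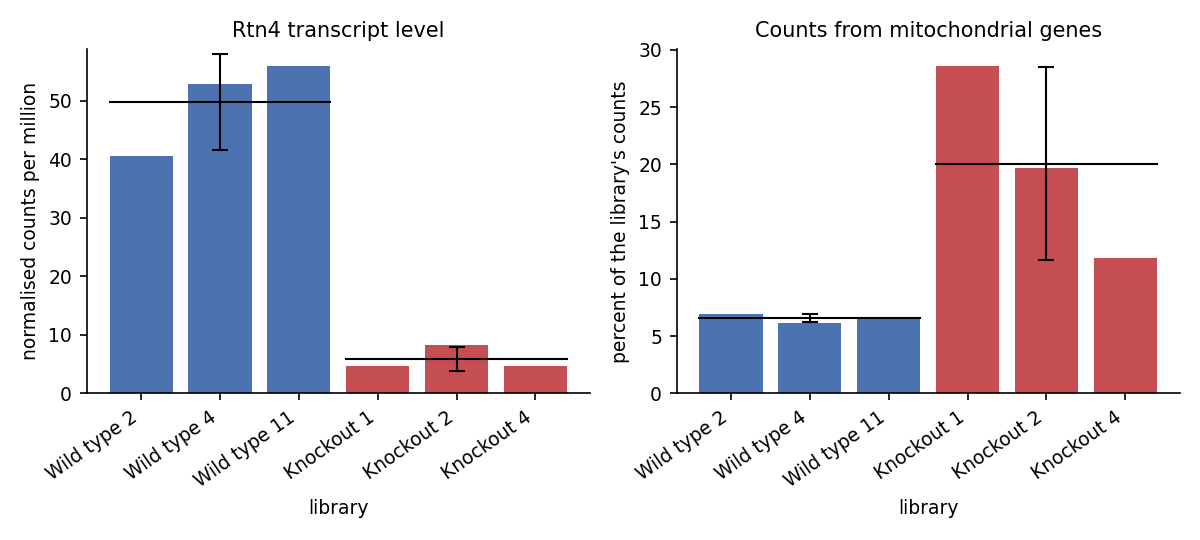
The left panel plots the Rtn4 level of each library in normalised CPM, and the right panel plots the percent of each library's counts that came from mitochondrial genes. Bars are libraries (wild type blue, knockout red), black lines are group means and error bars are ± 1 SD (n = 3). Rtn4 lay at 4.64 to 8.22 in knockout against 40.5 to 56.0 in wild type, and the mitochondrial share lay at 11.8% to 28.6% against 6.17% to 6.90%.

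Knockout and wild-type livers differed in 2268 of 13304 tested genes (edgeR, adjusted p under 0.05), of which 1165 rose and 1103 fell in knockout. At least 2-fold changes made up 701 of the rises and 654 of the falls. In 2252 of the called genes the 3 knockout levels did not overlap the 3 wild-type levels. Over all tested genes the share without overlap was 38.9%, where chance gives 10%. Called genes with the largest rises included Angptl8, a secreted regulator of lipoprotein lipase, from 27.1 ± 14.2 to 378 ± 277 CPM (3.80 ± 0.54). Obp2a, of the odorant-binding lipocalins, rose from 0.691 to 7.07 CPM (3.34 ± 0.37), and Cnbd2 from 0.681 to 7.43 CPM (3.43 ± 0.34). The B cell gene Pax5 (3.08 ± 0.63) and the mitochondrial mRNA mt-Co2 (3.27 ± 0.63) were also among the 10 largest rises. The value of mt-Co2 is uncertain, since 100% of its 50-base words are shared with other genes. The largest falls included Sacm1l, a phosphoinositide phosphatase of the endoplasmic reticulum, from 26.1 ± 6.98 to 1.63 ± 0.72 CPM (−3.98 ± 0.33). Echdc1 (−3.57 ± 0.50), which clears ethylmalonyl-CoA, Acss3, an acyl-CoA synthetase (−3.15 ± 0.35), and Folr2, a folate receptor of macrophages (−3.46 ± 0.58), fell as well. Ugt1a5 (−4.45 ± 0.71), Ugt1a9 (−3.20 ± 0.65) and Srp54a (−3.24 ± 0.38) also fell, but share 64.0%, 61.8% and 75.2% of their 50-base words with other genes, so their values are uncertain.

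The libraries also differed by genotype in their make-up. Mitochondrial genes took 6.90%, 6.17% and 6.71% of the counts in wild type 2, 4 and 11, and 28.6%, 19.7% and 11.8% in knockout 1, 2 and 4. The first principal component of the log2 CPM, with 62.4% of the variance, placed knockout 1, 2 and 4 at 67.3, 48.1 and 8.55 and the wild-type libraries at −49.8 to −32.2. The count of called genes was 827 without wild type 2, 630 without wild type 4, 1691 without wild type 11, 804 without knockout 1, 979 without knockout 2 and 4046 without knockout 4. With knockout 4 alone against the 3 wild types, a comparison chosen after the data had been examined, 25 genes were called, 16 higher and 9 lower. With a single knockout library the spread comes from the wild-type libraries alone and knockout is assumed to vary like them, so its p-values carry no spread between knockout mice. With the mitochondrial share as a covariate, edgeR called 0 genes (1146 at an unadjusted p under 0.05, and no other tool was run with it). Scaled by library totals, which moved the median of all genes to −0.16, 690 genes rose and 1566 fell, against 1165 and 1103 with TMM. The 128 named genes that were called had the same sign in each fit that left out 1 library and with knockout 4 alone. Their knockout levels did not overlap their wild-type levels, so this outcome was nearly built in and is no check of them. Of the 128, 62 passed in all 6 fits that left out 1 library. Summed over the 39 lists, with a gene counted in each list that holds it, 178 members were called by edgeR. The sum was 98, 68 and 151 without wild type 2, 4 and 11 and 82, 93 and 318 without knockout 1, 2 and 4, so the counts per list depend on which libraries are used. Over all tested genes 17.05% were called, and a list with a share of called members near or below that is not set apart by its count. This holds, among others, for the lists of fatty acid oxidation, bile acids, gluconeogenesis and AMPK, where it is not repeated below.

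For the insulin signalling pathway, the adaptor gene Irs1 fell in knockout liver while the receptor and its main kinase did not pass the test. Irs1, which links the insulin receptor to PI3-kinase, went from 5.97 ± 2.08 to 1.43 ± 0.43 CPM (−2.05 ± 0.37 SE, adjusted p = 0.00831). Smaller falls were seen in Shc1 (−0.65 ± 0.17), in Socs3, a feedback inhibitor of cytokine and insulin signals (−0.82 ± 0.21), and in Enpp1, an inhibitor of the receptor (−0.66). Prkce, a protein kinase C, rose (1.19). The values were −0.17 ± 0.20 for Insr, −0.23 ± 0.17 for Akt2, −0.03 ± 0.19 for Foxo1 and −0.90 ± 0.43 for Irs2, with adjusted p-values of 0.592, 0.355, 0.929 and 0.167. Of the 44 tested members of the list, 1 rose and 5 fell, the counts being 1 and 5 when adjusted over the list alone. The share of members called was below the 17.05% called over all tested genes. The list as a whole did not pass (median −0.16, camera adjusted p = 0.103), but did without wild type 11 (0.0204), with no low-count filter (0.0148), with the replicate block (0.0178), with the mitochondrial covariate (0.0154) and with knockout 4 alone (0.0361), all adjusted p-values. Its median against the wild-type mean was −0.17, −0.11 and −0.23 in knockout 1, 2 and 4, whose mitochondrial shares were 28.6%, 19.7% and 11.8%. In wild type 2, 4 and 11 it was 0.03, 0.14 and −0.17, so knockout 1 and 2 did not lie below wild type 11.

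Called genes of the FOXO1-induced and insulin-repressed list went both ways. Of 17 tested, 2 rose and 2 fell (2 and 2 when adjusted over the list alone). Igfbp1, a secreted IGF-binding protein that insulin represses, fell from 69.5 ± 27.5 to 8.59 ± 5.26 CPM (−3.02 ± 0.49), and Sesn3 fell (−0.93 ± 0.17). Angptl8 rose as above and G0s2, an inhibitor of the lipase ATGL, rose from 26.3 ± 9.34 to 186 ± 57.4 CPM (2.82 ± 0.32). Both are known as genes that insulin and feeding induce in liver, so they do not do what the name of the list says. The median of this list was −0.16, its mean 0.04, and camera gave an adjusted p of 0.81. G6pc (0.18 ± 0.28), Pck1 (0.42 ± 0.21) and Srebf1 (−0.10 ± 0.22) did not pass, and Fasn missed the threshold at −0.73 ± 0.24 (adjusted p = 0.0577).

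**Figure D2:**
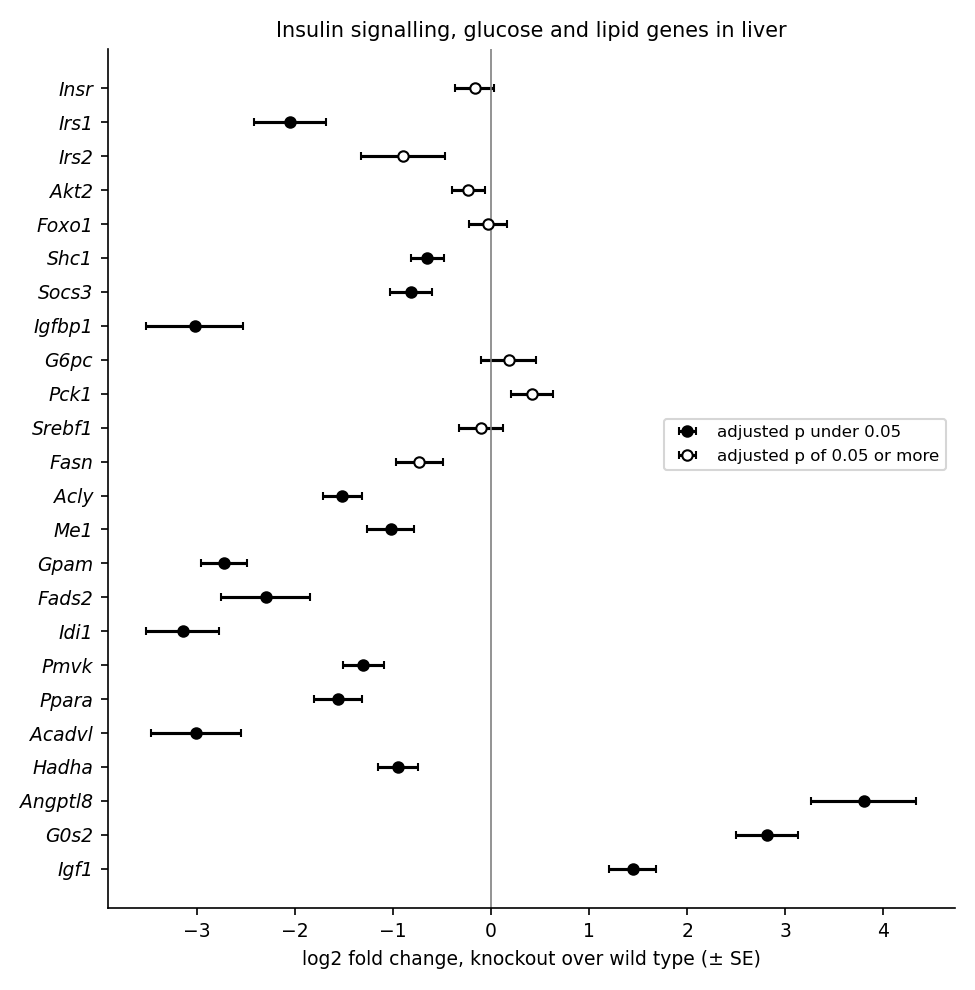
Log2 fold changes, knockout over wild type, of 24 genes of insulin signalling, glucose and lipid metabolism (edgeR, n = 3 each). Points are estimates and bars ± 1 SE, filled where the adjusted p was under 0.05, with Irs1 at −2.05, Gpam at −2.72 and Angptl8 at 3.80.

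Lipid-synthesis genes were lower in knockout liver. Gpam, which starts triglyceride synthesis, fell from 83.3 ± 14.8 to 12.6 ± 3.13 CPM (−2.72 ± 0.23, adjusted p = 0.00101). Acly, which makes cytosolic acetyl-CoA, fell from 416 ± 50.2 to 145 ± 25.2 CPM (−1.52 ± 0.20). The desaturase Fads2 (−2.30 ± 0.45) and the malic enzyme Me1 (−1.02 ± 0.24, with 27.0% of its words shared with other genes) fell as well. Of 29 tested genes of lipogenesis and triglyceride synthesis, 7 fell and 0 rose, and 9 fell and 1 rose when adjusted over the list alone. The list lay lower with camera (median −0.52, adjusted p = 0.00203; adjusted p = 0.691 with an estimated correlation). It passed in each fit that left out 1 library (adjusted p up to 0.00958). With knockout 4 alone, where only wild type supplies the spread, its adjusted p was 0.00232 and 1 of its genes fell and 0 rose. Its medians were −0.38, −0.64 and −0.37 in knockout 1, 2 and 4. Of 27 cholesterol synthesis genes 3 fell and 0 rose, by either adjustment, counted over all genes or adjusted over the list alone. They included the isomerase Idi1 (−3.15 ± 0.37) and the kinase Pmvk (−1.31 ± 0.21), and 21.3% of the 50-base words of Idi1 are shared with other genes. The share of these 27 genes called was below the 17.05% of all tested genes. The list lay lower (median −0.49, camera adjusted p = 0.00298; adjusted p = 0.9 with an estimated correlation). With knockout 4 alone its adjusted p was 0.0514.

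Several genes of fuel use fell too. Acadvl, which opens the oxidation of long-chain fatty acids, fell from 199 ± 26.3 to 24.7 ± 19.3 CPM (−3.01 ± 0.46). Ppara, the transcription factor of the fasting response, fell from 69.5 ± 22.3 to 23.5 ± 2.23 CPM (−1.57 ± 0.24), and Hadha fell as well (−0.95 ± 0.20). Of 38 genes of fatty acid oxidation and ketogenesis, 7 fell and 0 rose, and 8 fell and 0 rose when adjusted over the list alone (median −0.24, camera adjusted p = 0.0314; adjusted p = 0.9 with an estimated correlation). That call was lost without wild type 4 (0.0536), without knockout 2 (0.0977), with the replicate block (0.0657) and with knockout 4 alone (0.44), all adjusted p-values. Its medians were −0.37, −0.36 and −0.10 in knockout 1, 2 and 4. Of 35 genes of amino acid and urea metabolism, 7 fell and 0 rose, and 8 fell and 0 rose when adjusted over the list alone. Cps1, the first enzyme of the urea cycle, fell from 2922 ± 411 to 1016 ± 427 CPM (−1.52 ± 0.29), with Gnmt (−2.13 ± 0.45) and Bckdha (−2.56 ± 0.46). The list lay lower (median −0.27, camera adjusted p = 0.0321; adjusted p = 0.9 with an estimated correlation) but not without knockout 2 (0.225), with a filter of 1 CPM in 3 libraries (0.0521), with the replicate block (0.0634) or with knockout 4 alone (0.908), all adjusted p-values. Its medians were −0.37, −0.56 and 0.08 in knockout 1, 2 and 4, so the library with the smallest mitochondrial share, 11.8%, lay apart from the rest. Of 26 genes of bile acid synthesis and transport, 5 fell and 0 rose, and 5 fell and 1 rose when adjusted over the list alone. They were Klb, the co-receptor of FGF15 and FGF21 (−1.57 ± 0.23), Nr5a2 (−0.80 ± 0.21), the transporter Slco1b2 (−0.71 ± 0.20), Acox2 (−0.86 ± 0.26) and Akr1c6 (−1.18). The list lay lower (median −0.40, camera adjusted p = 0.0142; adjusted p = 0.9 with an estimated correlation). This call was lost without wild type 2 (0.084), wild type 4 (0.0795) or knockout 2 (0.0996) and with knockout 4 alone (0.352), all adjusted p-values. With the mitochondrial share as a covariate, the lists of fatty acid oxidation, amino acids and bile acids did not pass (adjusted p = 0.712, 0.557 and 0.255) and had medians of −0.01, 0.03 and −0.16.

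Carbohydrate genes changed in both directions. Of 24 genes of gluconeogenesis and glycogen, 4 fell and 0 rose, the same counts as when adjusted over the list alone (median −0.19, camera adjusted p = 0.113, but 0.0446 without knockout 1, 0.0347 with the replicate block and 0.0237 with no low-count filter). These included the glycogen enzymes Gbe1 (−1.40 ± 0.26) and Pygl (−1.08 ± 0.24) and Pcx, pyruvate carboxylase (−0.78 ± 0.20). Of 27 genes of glycolysis and fructose metabolism, 4 rose and 7 fell, and 5 rose and 9 fell when adjusted over the list alone (median −0.13, camera adjusted p = 0.317). Pdha1 fell (−1.72 ± 0.31), and Pgk1 fell (−1.82 ± 0.45) with 68.0% of its words shared with other genes. Txnip, a thioredoxin inhibitor that glucose induces, rose (1.25 ± 0.28), as did Aldoa (0.63) and Gapdh (2.97), a gene with many processed copies. Without knockout 1 the glycolysis counts were 0 and 1, and with knockout 4 alone they were 0 and 0 for both lists. Among 19 regulators of AMPK signalling and mitochondrial biogenesis, Sirt3 (−1.19 ± 0.23) and Prkag2 (−0.92 ± 0.19) fell and 0 rose, by both adjustments, the second being adjusted over the list alone (camera adjusted p = 0.771).

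Apolipoprotein and growth hormone genes showed opposite moves within their lists. Apoc1 rose from 3623 ± 565 to 9742 ± 2833 CPM (1.43 ± 0.26), Apoc3 from 2294 ± 310 to 5279 ± 1399 CPM (1.20 ± 0.24), and Apoc2 rose at 0.823 to 3.36 CPM (2.01 ± 0.48) with 88.2% of its words shared with another gene. Npc1, the lysosomal cholesterol transporter, fell (−0.95 ± 0.21), as did Mttp (−0.91), Abca1 (−0.68) and Scarb1 (−0.80). The list of LXR targets and lipoprotein transport counted 3 rises and 4 falls among 27 genes, and 6 and 7 when adjusted over the list alone (camera adjusted p = 0.353). Igf1, the growth hormone-induced hepatic hormone, rose from 522 ± 31.8 to 1423 ± 429 CPM (1.45 ± 0.24). Cish, an inhibitor that growth hormone induces, fell from 19.3 ± 16.7 to 3.67 ± 1.44 CPM (−2.40 ± 0.56). The growth hormone list, with Igfbp1 as its other fall, had 1 rise and 2 falls among 18 genes, also when adjusted over the list alone (median 0.01, mean −0.29, camera adjusted p = 0.996). Of 13 tested female-biased liver genes 4 fell and 0 rose, and 6 fell and 0 rose when adjusted over the list alone. They included Abcd2 (−1.61 ± 0.41), Cyp2b10 (−1.76 ± 0.46) and Cyp2a4 (−1.58 ± 0.49, with 38.0% of its words shared with other genes), the last 2 below 2 CPM. This list passed narrowly (median −0.78, camera adjusted p = 0.0321; adjusted p = 0.9 with an estimated correlation), but not without wild type 4 (0.097), without knockout 2 (0.132) or with knockout 4 alone (0.0707), all adjusted p-values. It also missed the threshold with a filter of 1 CPM in 3 libraries (0.101), limma-voom (0.0512), library totals (0.0534), length and GC trends removed (0.0562) and the mitochondrial covariate (0.0582). Of 22 male-biased genes 4 rose and 0 fell, also when adjusted over the list alone, including Cyp2u1 (1.39 ± 0.20) and Sult5a1 (1.53 ± 0.34). The male-biased list did not pass (camera adjusted p = 0.265), but did without knockout 2 (adjusted p = 0.0478) and with knockout 4 alone (adjusted p = 0.00706). The Y-linked gene Ddx3y was present in all 6 libraries, at 34.3 to 84.2 CPM.

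Marker genes of lymphocytes and neutrophils were higher in knockout liver, from low levels. Of 12 tested T and NK cell markers 6 rose and 0 fell, and 9 rose and 0 fell when adjusted over the list alone. Ccl5 rose from 0.542 ± 0.087 to 3.20 ± 1.35 CPM (2.56 ± 0.42), and the T cell receptor genes Trbc1 (2.02 ± 0.41) and Trbc2 (from 0.930 ± 0.33 to 3.77 ± 1.41 CPM), which share sequence, rose with it. Of 16 B and plasma cell markers 8 rose and 0 fell, and 11 rose and 0 fell when adjusted over the list alone, with Cd79a at 1.95 ± 0.34 and Ighd at 2.11 ± 0.40. All 3 tested neutrophil markers, of 15 fixed, rose, also when adjusted over the list alone: S100a8 (2.37 ± 0.42), S100a9 (1.81 ± 0.42) and Csf3r (1.97 ± 0.39). The T and NK cell list (median 1.35, camera adjusted p = 6e-06) and the B and plasma cell list (median 1.47, adjusted p = 2.67e-06) passed in every fit that left out 1 library, but both gave an adjusted p = 0.691 with an estimated correlation. The counts of called genes were less stable: the 6 of the T and NK cell list became 2 without wild type 2, 1 without wild type 4 and 3 without knockout 2, and the 8 of the B and plasma cell list became 5 without wild type 2 or knockout 2. Medians of the B and plasma cell list were 1.02, 1.40 and 0.59 in knockout 1, 2 and 4, whose mitochondrial shares were 28.6%, 19.7% and 11.8%. With 0.5 CPM added to these low levels, they are smaller than the list's median of 1.47 and not on its scale. With knockout 4 alone, where only wild type supplies the spread, adjusted p-values were 6.15e-05 and 0.00251, and 0 genes of either list were called by edgeR.

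Interferon-response genes rose in part, with 4 of 35 higher and 0 lower, also when adjusted over the list alone. They were Stat2 (1.20 ± 0.25), Oas2 (2.18 ± 0.47), Ifit1 (1.62 ± 0.46) and Irgm1 (1.21 ± 0.33). The share of the 35 genes called was below the 17.05% of all tested genes. The list did not pass (median 0.57, camera adjusted p = 0.0603), and passed without wild type 11 (0.00715), without knockout 1 (0.00396) and without knockout 4 (0.0304), all adjusted p-values. It also passed with limma-voom (0.0244), library totals (0.0227), length and GC trends removed (0.045), no low-count filter (0.0389) and the replicate block (4.53e-07). That block rests on 4 libraries and on pairs that are not assumed. The interferon list had medians of 0.09, 1.21 and 0.13 in knockout 1, 2 and 4, and without knockout 2 its camera adjusted p was 0.731. In wild type 2, 4 and 11 the medians were −0.075, −0.33 and 0.43, so knockout 1 and 4 lay within the wild-type range. Among 34 inflammation and acute-phase genes, 5 rose and 4 fell, and 6 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.964). Crp (−1.12 ± 0.27), Serpina3m (−1.49 ± 0.22), Stat3 (−0.73 ± 0.18) and Socs3 fell, while Il1r1 (0.92 ± 0.23), Saa3 (1.68), Hamp (1.95), Orm1 (0.75) and Orm3 (0.90) rose.

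Markers of other liver cells moved differently from those of lymphocytes. Of 22 endothelial markers 5 fell and 0 rose, also when adjusted over the list alone. They were Oit3 (−1.45 ± 0.26), Lyve1 (−1.69 ± 0.32), the VEGF receptor Kdr (−0.92 ± 0.21), Clec4g (−0.81) and Ptprb (−0.70). The list lay lower (median −0.44, camera adjusted p = 0.0115, and 0.9 with an estimated correlation) with medians of −0.09, −0.36 and −0.87 in knockout 1, 2 and 4. In wild type 2, 4 and 11 the medians were 0.006, −0.18 and 0.18, so knockout 1 lay within the wild-type range. The endothelial list did not pass without knockout 4 (camera adjusted p = 0.224). Its count of 5 became 2 without wild type 2 or knockout 2 and 3 without wild type 11. Of 11 cholangiocyte markers 4 fell and 0 rose, also when adjusted over the list alone: Atp1b1 (−1.04 ± 0.26), Pkhd1 (−1.18 ± 0.32), Epcam (−1.30 ± 0.38) and Clu (−1.24), with a camera adjusted p of 0.0849. The cholangiocyte list passed without wild type 2 (0.039), without knockout 1 (0.0224), with no low-count filter (0.0369), with the replicate block (0.031), with the mitochondrial covariate (0.0486) and with knockout 4 alone (0.0374), all adjusted p-values. By edgeR 0 of its genes were called without wild type 2, wild type 4, knockout 1 or knockout 2, and 2 without wild type 11. Epcam passed in 0 of the 6 fits that left out a library (highest adjusted p = 0.154). Of 21 Kupffer cell and macrophage markers Folr2 fell and Itgax rose (1.56 ± 0.45), and 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.996). The macrophage list had medians of −0.16, 0.52 and −0.48 in knockout 1, 2 and 4. In wild type 2, 4 and 11 the medians were −0.157, −0.217 and 0.254, so knockout 1 lay within the wild-type range. Without knockout 2 the median of the macrophage list was −0.46 and 4 of its genes fell. None of 17 stellate cell and fibroblast markers was called by edgeR, also when adjusted over the list alone, with a list median of 0.21 (camera adjusted p = 0.645). Among 17 periportal hepatocyte markers Sdhd (−1.10 ± 0.25) and Hsd17b13 (−0.94 ± 0.25) fell and 0 rose, and among 18 pericentral markers Tbx3 (1.59 ± 0.22), Sp5 (1.82 ± 0.35) and Axin2 (1.15 ± 0.31) rose and 0 fell. Both pairs of counts were the same when adjusted over the list alone, and the camera adjusted p-values were 0.393 and 0.763. Tbx3, Sp5 and Axin2 are known targets of Wnt signalling.

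**Figure D3:**
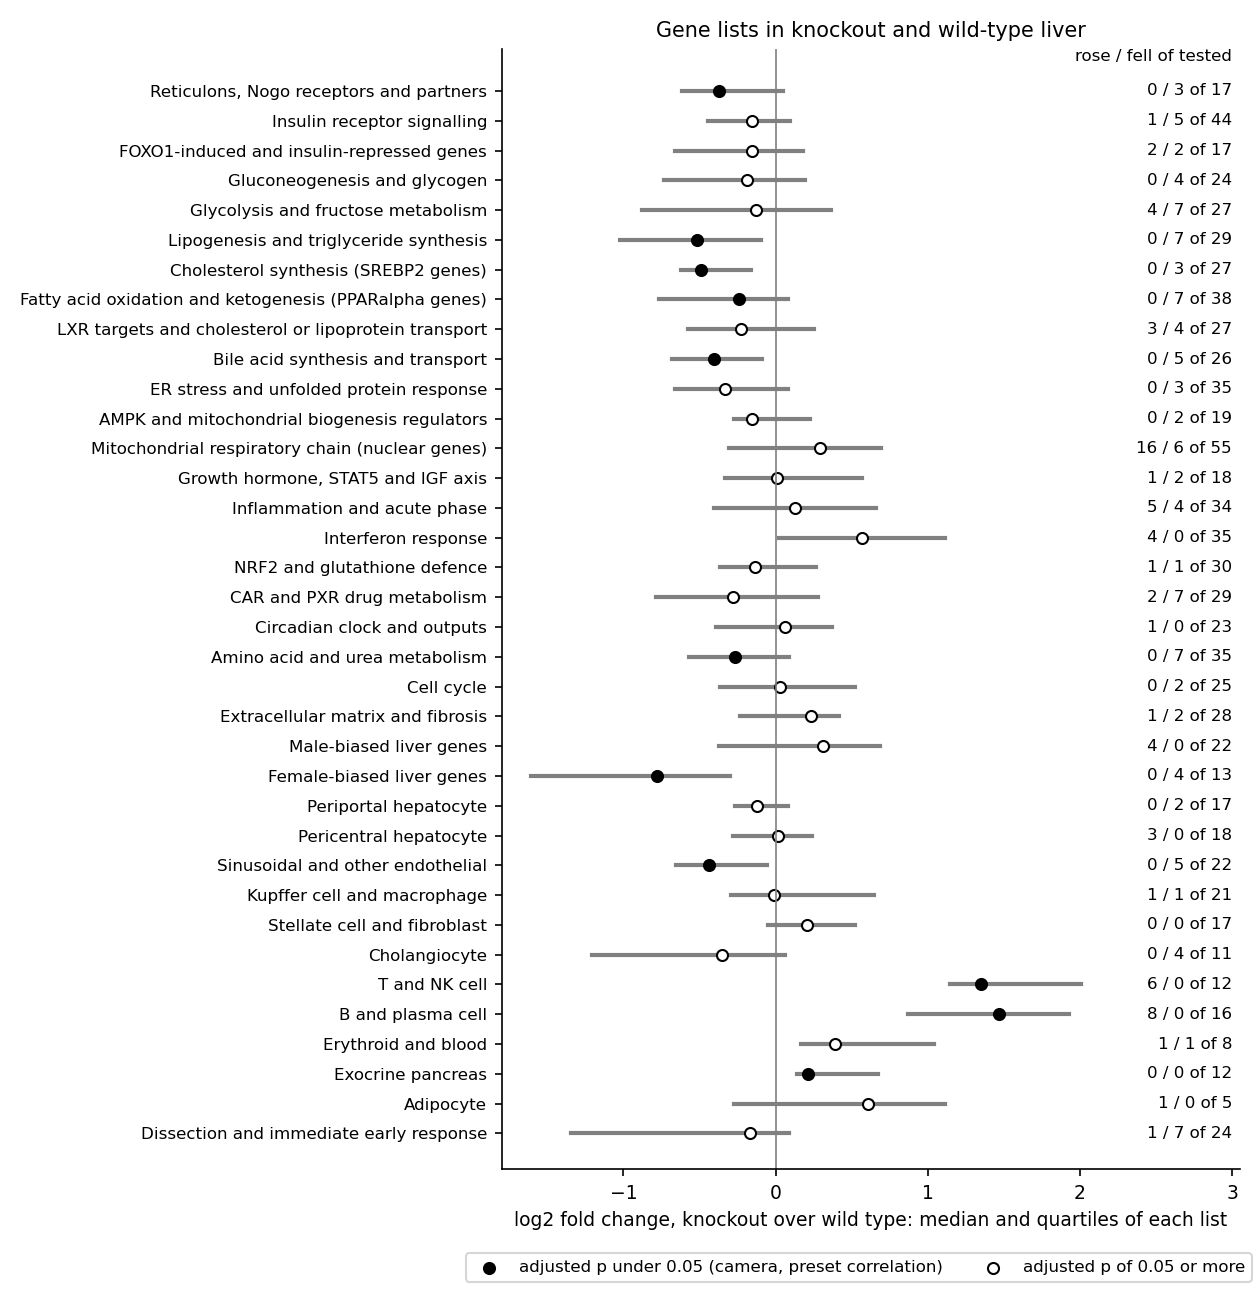
Median log2 fold change, knockout over wild type, of the 36 gene lists with at least 5 tested members (points), with the lower and upper quartiles of their members (grey bars). Filled points passed camera with the preset correlation of 0.01 (adjusted p under 0.05), the reticulon list only with Rtn4 in it, and the numbers at the right count members that rose and fell. The B and plasma cell list had the highest median, at 1.47, and the female-biased list the lowest, at −0.78.

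All 13 mitochondrially encoded mRNAs rose in knockout liver, by 1.66 (mt-Co1, SE 0.33) to 3.27 (mt-Co2, SE 0.63) on the log2 scale. Their median was 1.94 (camera adjusted p = 3.37e-09; adjusted p = 0.173 with an estimated correlation), and 2.66, 1.77 and 1.10 in knockout 1, 2 and 4. This list was made after the data had been examined, and all 13 also rose when adjusted over the list alone. The mt-Co1 level was 20650 to 23090 CPM in wild type and 102400, 65120 and 40810 CPM in knockout 1, 2 and 4. Transcripts of mt-Co2 share 100% of their 50-base words with other genes, and its level is uncertain. The largest rises, 2.86 to 3.27 in mt-Co2, mt-Co3, mt-Atp8 and mt-Nd4l, were in genes far below mt-Co1, at 4.27 to 142 CPM in wild type. Also low there were mt-Atp6 and mt-Nd3 (19.2 to 191 CPM), with rises of 1.99 and 1.92. Why these genes were low was not tested, so the upper end of the range is uncertain. The remaining genes rose by 1.66 to 1.99. Nuclear genes of the respiratory chain went both ways. Of 55 tested, 16 rose and 6 fell, and 20 rose and 10 fell when adjusted over the list alone. Ndufa3 (1.10 ± 0.19), Ndufb7 (1.01) and Cox7c (1.04 ± 0.20) were among the rises, the last with 53.0% of its words shared with other genes, and Sdha (−1.63 ± 0.32) and Atp5b (−1.52) were among the falls. The list did not pass (median 0.29, camera adjusted p = 0.113), but did without knockout 2 (adjusted p = 0.00958), with the mitochondrial covariate (adjusted p = 0.00016) and with knockout 4 alone (adjusted p = 2.21e-06, only wild type supplying the spread). Without knockout 4 its camera direction was down (adjusted p = 0.847, median 0.05) with 19 rises and 17 falls, so the upward lean rests on knockout 4. The counts were 3 and 3 without wild type 2, 1 and 2 without wild type 4 and 6 and 2 without knockout 1. Its medians were 0.15, −0.08 and 0.47 in knockout 1, 2 and 4. When scaled by library totals its counts were 10 and 10. The median transcript of this list had 865 bases. All nuclear protein-coding genes under 1000 bases, those of this list in part among them, had a median log2 fold change of 0.28, near that of the list.

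Across all 36 tested lists 11 passed camera with the preset correlation, 7 of biology and 4 of markers, and 10 with Rtn4 left out of its list. With an estimated correlation 0 passed (lowest adjusted p = 0.691), as by the directional test of fry (lowest adjusted p = 0.059), while the mixed test of fry, which takes changes in either direction, passed 26. Of the 11, 5 also passed with knockout 4 alone against wild type and 5 with the mitochondrial covariate. Fold changes leaned on transcript properties, with a Spearman correlation across 11878 protein-coding genes of −0.12 with transcript length and 0.18 with GC content, genes not being independent replicates.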

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

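The fits with knockout 4 alone, with mitochondrial genes left out, with the mitochondrial share as a covariate, with length and GC trends removed, with library totals and with Rtn4 left out of its list were chosen after the results had been seen, and all others before. The count of 2268 called genes ran from 2184 to 3330 over the other scalings by size factors, low-count filters and tools, and from 2237 to 2283 with library totals, without mitochondrial genes or with length and GC trends removed. Upper-quartile scaling split its 2338 calls into 1421 higher and 917 lower. Leaving out 1 library gave 630 (without wild type 4) to 4046 (without knockout 4) genes, with 827 without wild type 2, 804 without knockout 1 and 979 without knockout 2. Fewer libraries leave less power, which does not account for the higher count without knockout 4, the knockout library nearest to wild type on the first principal component, and the cause was not tested. Knockout 4 alone gave 25 genes and the mitochondrial covariate 0 by edgeR (1146 at an unadjusted p under 0.05, no other tool run). That share was higher in each knockout library than in each wild-type library, so the covariate takes up much of the difference between genotypes. By construction, a further 2-fold minimum gave 1355 genes and an adjusted p under 0.1 gave 3589. With the replicate block on the shared numbers 2 and 4 (4 libraries) 1588 genes were called, against 301 in the same 4 libraries without it, and the cause was not tested. The deviations of same-numbered libraries did not correlate across genes (r = −0.01), and 2 shared numbers are too few to show pairs, so no pairing is assumed. Of the 2268 calls, 2 changed sign with knockout 4 alone, 27 with the covariate, 1 with length and GC trends removed and 0 in the other settings. In 2252 of them the genotypes did not overlap, so kept signs in fits that drop libraries were nearly built in.

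Rtn4 ranged from −3.41 to −2.85 over all settings and passed in each except with the mitochondrial covariate (−3.03, adjusted p = 0.189, the highest over its settings), where the fold moved little and the call ended. The 11 gene lists became 20 with no low-count filter, the cause of which was not tested, and 0 with an estimated inter-gene correlation. Leaving out 1 library gave 8 to 14 lists and the other settings 8 to 12, but not always the same lists. Of the 11, 5 also passed with the covariate or with knockout 4 alone, 7 with the replicate block, in the same 4 libraries without it, without wild type 4 or without knockout 2, and 8 to 11 in each other setting except the estimated correlation. Among the named genes, the calls weakened were 57 without wild type 4, 52 without knockout 1, 46 without wild type 2, 44 without knockout 2, 16 without wild type 11 and 3 without knockout 4. They were 127 with the covariate and 22 with the replicate block, and none turned direction in these settings or with knockout 4 alone. For fits that drop libraries this was nearly built in, as above. At this depth the self-test recovered 41.0% of 2-fold changes, so genes that did not pass are not shown to be equal.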

Other observations

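The tests of a gradient of RNA condition, of normalization, of a joint rise with nuclear genes, of the share of cytosolic mRNA, of the share of hepatocytes and of blood were chosen only after their results had been seen. The fit with length and GC trends removed and the lists of ribosomal protein and nuclear-retained RNAs were also added after the data had been examined.

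Heat-shock and immediate early genes were lower in knockout liver in part. Of 24 tested, 7 fell and 1 rose, also when adjusted over the list alone, with Myc from 16.0 ± 3.53 to 2.45 ± 0.44 CPM (−2.71 ± 0.25 SE), Gadd45g at −2.34 ± 0.24 and Hspa1b, which has a near-identical copy, at −1.94 ± 0.25. Hsph1 fell (−1.61) and Ier2 rose (0.88). The list did not pass (median −0.17, mean −0.52, camera adjusted p = 0.108), but did without wild type 2 (adjusted p = 0.00274), without knockout 1 (0.0446), with no low-count filter (0.0269), with the mitochondrial covariate (0.005) and with knockout 4 alone (0.0361). Of 29 genes of CAR and PXR drug metabolism, 2 rose and 7 fell, and 2 rose and 9 fell when adjusted over the list alone (camera adjusted p = 0.103, but 0.00807 with no low-count filter, 0.0338 with the mitochondrial covariate and 0.0361 with knockout 4 alone). Cyp2c29 fell from 1203 ± 105 to 255 ± 165 CPM (−2.24 ± 0.38), with Aldh1a1 (−1.32 ± 0.29) and Cyp3a13 (−0.99 ± 0.20), while the receptor gene Nr1i2 rose (0.60). Ugt1a6a rose (1.37 ± 0.27) and Ugt1a1 fell (−2.93), but these genes share exons, and the 5 tested genes of the family together went from 167 to 30.9 CPM. Of 35 genes of the unfolded protein response Canx (−1.01 ± 0.26), Chac1 (−1.42 ± 0.37) and Edem1 (−0.62 ± 0.19) fell and 0 rose, and 0 fell and 0 rose when adjusted over the list alone by edgeR (camera adjusted p = 0.0667). The share of this list called was below the 17.05% of all tested genes. That list passed without wild type 11 (0.0384), without knockout 4 (0.00285), with limma-voom (0.0475) and with no low-count filter (0.00881), all camera adjusted p-values. Its medians were −0.67, −0.40 and 0.07 in knockout 1, 2 and 4. In wild type 2, 4 and 11 they were 0.02, 0.12 and −0.12, so knockout 4 lay within the wild-type range.

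Smaller groups had few changes. Of 30 NRF2 and glutathione genes Sod1 rose (0.64 ± 0.19, with 23.1% of its 50-base words shared with other genes) and Gsta3 fell (−1.30 ± 0.28), and 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.767). Of 23 clock genes Ciart rose (1.54 ± 0.34) and 0 fell (adjusted p = 0.767), of 25 cell cycle genes Ccnd1 (−1.05 ± 0.23) and Pcna (−0.85 ± 0.24, with 31.8% of its words shared) fell and 0 rose (0.996), and of 28 matrix genes Mmp14 rose (1.25 ± 0.30) and Fn1 (−1.25 ± 0.26) and Tgfbr2 (−0.86 ± 0.20) fell (0.996). Adjusted over the list alone the counts were the same, except that 1 cell cycle gene fell. Of 12 exocrine pancreas genes 0 were called by edgeR, also when adjusted over the list alone, though the list passed camera (adjusted p = 0.0344; adjusted p = 0.9 with an estimated correlation). That call was lost with upper-quartile scaling (0.0655), length and GC trends removed (0.0638), the replicate block (0.228) and the mitochondrial covariate (0.054), and without wild type 4 (0.097), wild type 11 (0.338, median −0.26) or knockout 4 (0.179), all adjusted p-values. Ctrb1 had 409, 30 and 1 counts in wild type 2, 4 and 11 and 123, 147 and 113 in knockout 1, 2 and 4, and without wild type 2 the list had 10 rises. Among 8 erythroid genes Hba-a2 rose and Alas2 fell (−1.05 ± 0.26), among 5 adipocyte genes Lpl rose (1.37 ± 0.35), and 1 tested muscle gene, Mylpf (1.53 ± 0.40), and 1 of 3 gut genes, Lgals4 (2.28 ± 0.31), rose. Camera adjusted p-values were 0.504 for the erythroid and 0.446 for the adipocyte list, and the last 2 lists were too small for it. Adjusted over the list alone, 2 adipocyte genes rose and the other counts stood. Of 80 cytosolic ribosomal protein genes 26 rose and 1 fell, Rpl3 (−1.19), and 30 rose and 4 fell when adjusted over the list alone (median 0.33, camera adjusted p = 2.61e-05; adjusted p = 0.336 with an estimated correlation). Many have processed copies. These genes are short, with a median transcript of 836.5 bases. All nuclear protein-coding genes under 1000 bases, these in part among them, had a median of 0.28, near that of the list. Since the sets overlap, this cannot decide whether the rise is particular to ribosomal proteins, and their share of calls was not compared with that of other short genes. Within 10 Mb of Rtn4, 8 of 66 tested genes were called (12.1%) against 17.0% elsewhere (Fisher's exact test, odds ratio 0.671, p = 0.329, genes not being independent).

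The 2268 called genes form the first pattern. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, of which 1, the real one, gave as many genes, with 0 as the highest of the others. Removing length and GC trends left 2237 calls, 1858 of them shared, and genes without shared 50-base words were called at 14.96% against 17.1% of all, which argues against either as the whole cause, though genes with at least 20% of words shared were called more often (30.2%). A gradient of RNA condition stays open, and how much of the calls it may account for cannot be told. The median change of the called genes in knockout 4 was 0.579 of that in knockout 1, where its excess of mitochondrial share was 0.237 of that in knockout 1. The genes were called with knockout 4 among the libraries, which favours genes changed in it and can raise the first ratio. Each knockout library had a higher mitochondrial share than each wild-type library, so this gradient and the genotype, itself untested further, cannot be told apart for these genes.

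The rise of the 13 mitochondrially encoded mRNAs is the second pattern. Their median stayed at 1.72 or more under 4 scalings, which argues against normalization. The upper quartile of nuclear respiratory chain genes was 0.69, below the lowest mitochondrial mRNA at 1.66, which argues against a joint rise of the same size in both. It cannot decide on a smaller rise of the nuclear genes, of which 16 of 55 rose and 6 fell. A lower share of cytosolic mRNA remains a candidate explanation, since 12 of 12 nuclear-retained RNAs were higher (median 0.80, camera adjusted p = 0.000103; adjusted p = 0.173 with an estimated correlation) and 5 rose, namely Neat1, Rn7sk, Firre, Snhg11 and Snhg14 (6 rose and 0 fell when adjusted over the list alone). These 12 passed the filter out of 21 on the list, and a low RNA can pass it through the libraries where it is high, which favours positive values. As whole classes, 226 long intergenic non-coding RNAs (median 0.46, 40 rose and 4 fell) and 208 antisense RNAs (median 0.51, 37 rose and 5 fell) were higher too. The upper quartile of the nuclear-retained RNAs, 1.49, fell short of 1.66 by less than the SE of 0.33 of mt-Co1. Against this explanation, their medians were 0.742, 0.725 and 0.623 in knockout 1, 2 and 4, without the gradient of the mitochondrial mRNAs (2.66, 1.77 and 1.10), though their fold changes spread widely (quartiles 0.30 and 1.49). So whether it covers the whole rise cannot be told apart from an effect of the genotype on mitochondrial RNA, which was not tested.

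The third pattern is the rise of lymphocyte and neutrophil markers, of which 17 of 31 rose and 31 of 31 were positive (median 1.503, lower quartile 1.14). These 31 passed the filter out of 19, 18 and 15 markers fixed for T and NK cells, B and plasma cells and neutrophils. A low marker can pass it through the knockout libraries where it is high, which favours positive values. With no low-count filter 8 of 19, 9 of 18 and 6 of 15 rose and 0 fell, with medians of 1.21, 1.34 and 1.97. The highest upper quartile among the endothelial, macrophage and stellate lists was 0.65, below the markers' lower quartile of 1.14, which argues against a lower share of hepatocytes. The markers' median lay at the percentile 100 of 10000 random lists matched on abundance (99th percentile 0.56), which argues against a general shift of low-abundance genes. Blood left in the tissue could be part of it. The 4 hemoglobin genes had a median of 0.55, with Hbb-bs at 0.19 and Hba-a2 at 1.56, an uncertain value since 86.9% of its words are shared with other genes. The 4 genes summed to 802, 331 and 394 CPM in knockout 1, 2 and 4 against 208 to 419 CPM in wild type. Knockout 2 and 4 thus lay below the 419 CPM of wild type 11. Their T and NK cell medians were 1.28 and 0.70 and their B and plasma cell medians 1.40 and 0.59, against 0.06 and 0.29 in wild type 11. These values argue against blood as the whole cause in knockout 2 and 4, and whether it is a part cannot be told apart. More immune cells in the knockout livers remain as an untested hypothesis, and the markers are low, with a median of 0.788 CPM in wild type and 2.66 CPM in knockout.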
